A study of Homo sapiens with 10 samples.

How the data were processed

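Total RNA of K562 cells, a human chronic myeloid leukaemia line that carries the BCR-ABL1 fusion, and of the microvesicles these cells release was measured on 10 Affymetrix HG-U133 Plus 2.0 arrays, 5 per group. Per the labels' protocols, RNA was isolated with Trizol in 5 independent experiments and biotin-labelled cRNA was prepared from it. The labels do not say whether cells and microvesicles with the same number came from 1 culture, so p-values measure the spread between these preparations. The deposited values are log2 expression values per probe set made with RMA, per the submitters' processing notes, with 1 column per array. RMA subtracts background, makes the distribution of probe intensities alike on all arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here. RMA assumes that most of the intensity distribution is shared between samples, so a different total amount or make-up of RNA in microvesicles is not visible as such in these values. They carry no detection call, and no filter on dim probe sets was applied in the main test. For arrays, their number limits the precision.

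The table holds 54630 probe sets, of which 17 are control probe sets, 41091 are annotated with 1 gene, 1801 with several genes and 11721 with none listed. Gene symbols came from the platform annotation and 41037 of the probe sets with 1 gene were named through the gene number in the reference table. Each gene was represented by the probe set with the highest mean over all 10 arrays, and probe sets with several genes or none were left out, which gave 19775 genes. Of these, 10523 had more than 1 probe set, and 1418 of those (13.48%) had probe sets past the threshold in both directions.

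Microvesicles were compared with cells by limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with 1 mean per group, 2-sided, and Benjamini-Hochberg adjustment over all 19775 genes. A gene passed at an adjusted p under 0.05, and a second count took those with a change of at least 1 on the log2 scale. Changes are microvesicles minus cells on the log2 scale, given ± SE, and group means are given ± SD. The 35 gene lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The 3' minus 5' difference of the ACTB and GAPDH control probe sets was compared by an exact permutation test of group means, with 6 measures of the arrays adjusted together. The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean was at least 6, without uncharacterised or antisense symbols. It added up to 2 rises and 2 falls from each list and 14 genes chosen whatever their values. Together 156 genes were selected, and the text gives those that illustrate each group.

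The lists cover cytosolic ribosomal proteins, translation factors, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, replication-dependent histones, erythroid genes, platelet, myeloid and lymphocyte markers, BCR-ABL1, RAS-MAPK, PI3K-AKT-mTOR and JAK-STAT signalling, apoptosis regulators, G1/S and G2/M cell cycle genes, immediate early genes, chaperones, the unfolded protein response, vesicle formation, the cytoskeleton, glycolysis, cholesterol synthesis, the proteasome, splicing, small nucleolar RNA host genes, nuclear-retained long noncoding RNAs, interferon response, cytokines, angiogenesis, DNA repair, ZNF genes, small nucleolar RNAs and microRNA genes.

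The gene test was tested on simulated data with 19775 genes and 5 arrays per group, in which 50 genes were changed at each size. It recovered 1 of 50 genes at 0.5, 29 at 1, 47 at 2 and 50 at 3 on the log2 scale, with 20 false calls. In the same simulation camera found the 1 shifted list and called 0 of 9 unshifted lists. The simulated genes varied independently and few were changed, while here 66.64% passed and estimated correlations within lists reached 0.91. These recovery and false call counts may therefore not carry over to the arrays. Alternatives covered the replicate number as a block, centring arrays on their median, quantile normalization of the table again, filters on dim genes, the mean of a gene's probe sets, each probe set by itself, a variance trend with robust fitting, array weights, an exact rank sum test, fry (which tests a list against no change and not against other genes) and leaving out each array. Loess normalization by level (each array fitted against the mean array) was added after a shift that depends on level had been seen. Also chosen then was the comparison of each list's median with 10000 random lists matched on mean level, which describes these arrays and is not a test.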

Results

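Gene expression was measured in 5 preparations of K562 cells and 5 of the microvesicles released by them. Microvesicles are membrane-bound particles that cells shed into the medium and that carry RNA of the parent cell. The comparison asks how the RNA content of microvesicles differs from that of the cells. Over the 19775 genes, Pearson correlations between arrays were 0.992 to 0.998 among cells, 0.925 to 0.955 among microvesicles and 0.870 to 0.925 between the groups (across genes, which are not independent replicates). The median SD of a gene was 0.147 in cells and 0.454 in microvesicles. Array medians were 4.10 ± 0.015 in cells and 4.26 ± 0.022 in microvesicles (SD, n = 5 each, exact permutation p = 0.00794, the smallest possible), a shift of 0.16. The spread over the probe sets of an array, as SD, was 2.34 ± 0.016 in cells and 1.94 ± 0.047 in microvesicles (SD, n = 5 each, exact permutation p = 0.00794). The Alu control probe set stood at 13.89 ± 0.063 and 13.51 ± 0.27 (SD, n = 5 each, exact permutation p = 0.0238).

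Control probe sets for RNA integrity and for 18S ribosomal RNA differed between the groups. The 3' minus 5' difference of the ACTB control probe sets was 2.39 ± 0.15 in cells and 3.12 ± 0.34 in microvesicles (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0119 over 6 measures). For GAPDH it was 0.449 ± 0.064 and 0.62 ± 0.13 (SD, n = 5 each, exact permutation p = 0.0159, adjusted p = 0.019). The mean of the 18S ribosomal RNA control probe sets was 12.15 ± 0.26 in cells and 10.56 ± 0.38 in microvesicles (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0119).

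Values were much lower in microvesicles than in cells for CD46, a complement regulator, and the gap junction gene GJA1. The same held for the early growth response factor EGR1 and the spindle gene ASPM. CD46 was 10.43 ± 0.18 in cells and 5.60 ± 0.79 in microvesicles (SD, n = 5 each), a change of -4.83 ± 0.31 on the log2 scale (28.5-fold lower, limma adjusted p = 1.62e-07). Its other probe sets changed by less, -2.59 and -2.72. GJA1 changed by -4.61 ± 0.37, EGR1 by -4.35 ± 0.24 and ASPM by -4.33 ± 0.27 (limma adjusted p = 8.38e-07, 1.10e-07 and 1.60e-07). After loess normalization by level CD46 stood at -4.00, GJA1 at -3.78, EGR1 at -3.53 and ASPM at -3.47. The glycosyltransferase gene GALNT7, the scaffold gene AKAP9, the adhesion gene CD58, the lipid transfer gene VPS13A, the thiamine transporter gene SLC19A2, TTC14, the DNA damage kinase ATR and PCNX4 made up the 12 largest falls under the rule for named genes, between -4.16 and -3.93. The rule admits only genes whose groups do not overlap, so the lack of overlap in these 12 is a condition and not a result. PCNX4 rests on 1 of its 7 probe sets, with 2 past the threshold the other way, and its mean over probe sets was -0.20 (adjusted p = 0.149). With the mean of a gene's probe sets AKAP9 changed by -1.74, VPS13A by -1.57, CD58 by -2.19 and ATR by -2.21. In microvesicles PCNX4 (3.02), VPS13A (3.52), ATR (3.86), SLC19A2 (3.94) and AKAP9 (3.96) lay below the median of the arrays. Without a detection call these values are not known to exceed background, so the size and order of these falls are uncertain. The same limit holds for the size of changes given below where a group mean lies under the array median. Examples are FTX (3.33) and TAF1D (3.68) in microvesicles and OAS1 (2.89) in cells.

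Under the rule for named genes, the largest rises were those of the galanin receptor gene GALR3 (3.34 ± 0.18, 10.1-fold, limma adjusted p = 1.10e-07), the ribosomal protein gene RPL27A (3.08 ± 0.17), the growth factor receptor gene EGFR (3.05 ± 0.30) and the ligand gene WNT6 (2.90 ± 0.22). ASB1, CYP4F12, ARHGAP33, SPG11, SPDEF, ZFTA, TMEFF2 and RPLP2 followed, with changes between 2.82 and 2.40. Here too the rule required groups that do not overlap. TMEFF2 ran from 5.99 to 9.56 over the microvesicle arrays. RPL27A and RPLP2 were read here from dimmer probe sets, and the bright probe sets of both genes, annotated with a small nucleolar RNA as well, stood at -0.042 ± 0.14 and -0.018 ± 0.14. SPG11 rose by 2.59 ± 0.41 in the probe set used here, from 6.05 in cells, and fell by 2.84 in another, from 8.73 in cells. The mean of its probe sets was -0.044. The rises of EGFR and WNT6 rest mostly on 2 of 9 and 1 of 4 probe sets, and the means over probe sets were 1.23 and 1.02. Those of ASB1 (1.52), ARHGAP33 (1.33), SPDEF (1.60), TMEFF2 (1.08) and RPLP2 (1.29) were also well below the change given above. After loess GALR3 stood at 4.20, RPL27A at 3.87, EGFR at 3.70 and WNT6 at 3.76, against -4.00 for CD46. Whether the largest fall or the largest rise was the larger thus depended on the scaling.

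**Figure D1:**
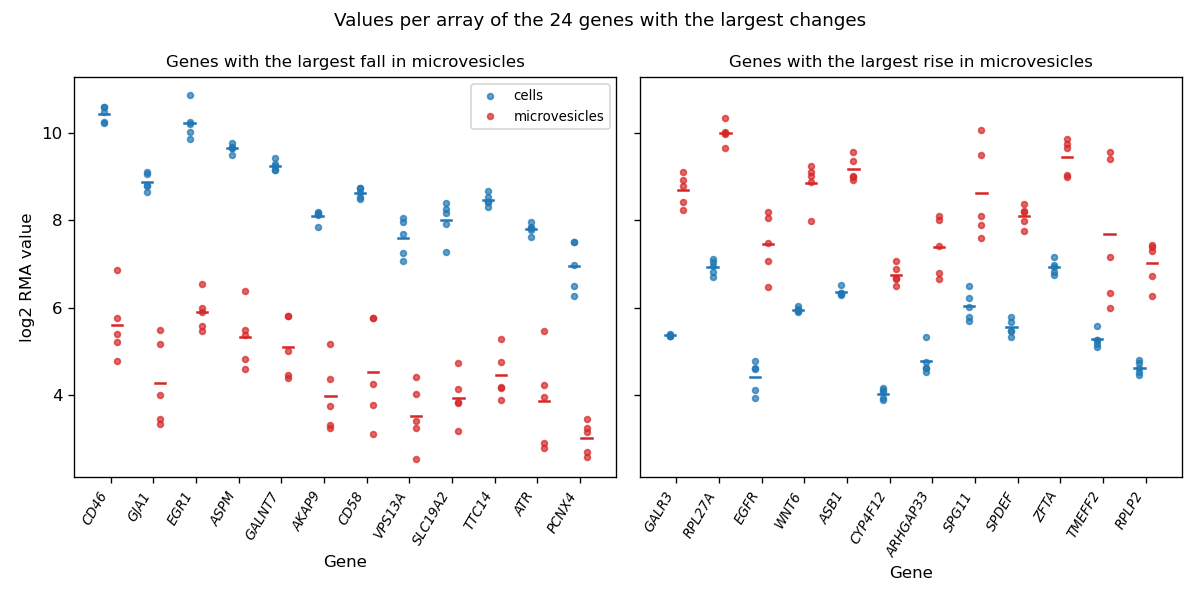
Log2 RMA values of the 24 genes with the largest changes under the rule for named genes, 12 falls on the left and 12 rises on the right; each point is an array (5 cells in blue, 5 microvesicles in red) and each bar a group mean. The cell and microvesicle points of a gene do not overlap because the rule required it. CD46 stood at 10.43 in cells and 5.60 in microvesicles and GALR3 at 5.36 and 8.70.

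Of the 19775 genes, 13179 (66.64%) passed the threshold, 7015 higher and 6164 lower in microvesicles, and 6142 of them changed at least 2-fold, 2221 higher and 3921 lower. The balance of these 2-fold changes depended on the scaling, with 1299 higher and 4589 lower after centring on the median, 2570 and 2050 after a second quantile normalization and 2241 and 1981 after loess. The groups did not overlap in 9876 genes (49.94%), against 0.794% by chance. With each array centred on its median the split was 5080 higher and 6868 lower. The median change over all genes was 0.20 (quartiles -0.76 and 0.70), and it depended on the level of the gene. Genes with a mean of up to 3 over the 10 arrays had a median change of 0.63 and those between 4 and 5 of 0.53, while those between 7 and 8 had -0.98 and those above 11 had -0.23. After loess normalization by level 8937 genes passed, 5327 higher and 3610 lower. Of the genes at least 2-fold lower, 2977 were lower and past the threshold after loess, and of those at least 2-fold higher, 1888 were higher.

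**Figure D2:**
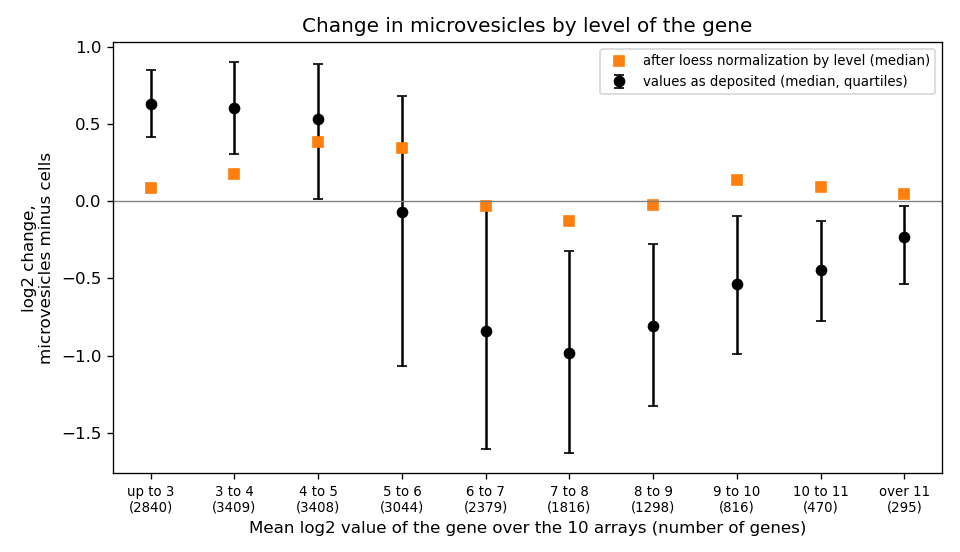
Median log2 change in microvesicles against cells for genes grouped by their mean log2 value over the 10 arrays (black, bars from the first to the last quartile), with the median after loess normalization by level in orange. Deposited values run from 0.63 in the dimmest genes to -0.98 between 7 and 8, and after loess the genes between 4 and 5 still lie at 0.38.

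Among genes chosen beforehand for this cell line, MYC fell by 1.17 ± 0.18 (limma adjusted p = 0.000149; -0.60 after loess and -0.70 after quantile normalization) and the nuclear RNA MALAT1 by 2.05 ± 0.35 (0.00029), the latter in all 12 of its probe sets. ABL1, the kinase partner of the fusion, changed by -0.49 ± 0.17 (limma adjusted p = 0.0242) and the erythroid factor GATA1 by -0.61 ± 0.15 (0.00368), but after loess they stood at 0.34 and 0.24 and after a second quantile normalization at 0.37 and 0.26, and ABL1 did not pass without cells replicate 1 (adjusted p = 0.0572) or 4 (0.0528). BCR did not pass (-0.16 ± 0.24), nor did ACTB (-0.27 ± 0.15), GAPDH (-0.24 ± 0.15) or the embryonic globin gene HBE1 (0.37 ± 0.18), and the signs of BCR and ACTB were positive after loess and after quantile normalization. With arrays centred on their median ACTB (-0.43, adjusted p = 0.0281) and GAPDH (-0.40, 0.0321) passed. HBE1 passed after loess (0.68, adjusted p = 0.00651) and after quantile normalization (0.66, 0.00971). HBG1 and HBG2 share their probe sets and were not tested as genes. The shared probe sets changed by -0.58 ± 0.23, -0.56 ± 0.22 and -0.59 ± 0.23. Adjusted over all probe sets, their limma p was 0.0367, 0.0389 and 0.035. The tetraspanin genes CD81 and CD9 fell by 2.12 ± 0.16 (-1.28 after loess) and 1.96 ± 0.30. CD9 rests on 1 of 3 probe sets, with the other 2 past the threshold the other way, and its mean over probe sets was -0.12 (adjusted p = 0.486). CD63, another tetraspanin, and the ESCRT gene TSG101 fell by 0.60 ± 0.19 and 0.89 ± 0.17, and neither passed after loess (-0.12 and -0.11).

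Cell cycle and DNA repair genes were lower in microvesicles. Of 53 G2/M genes measured, 45 fell and 0 rose (the same adjusted over the list alone), with a median change of -1.46 and -0.77 after loess. Camera placed the list below other genes (adjusted p = 7.62e-11), but not so when the correlation was estimated (adjusted p = 0.326 with an estimated correlation). The mitotic kinase TTK changed by -2.84 ± 0.28 and the cytokinesis gene ECT2 by -2.58 ± 0.23. Among 43 G1/S genes 40 fell and 1 rose (the same adjusted over the list alone), with a median of -1.39 and -0.67 after loess (camera adjusted p = 8.74e-09; adjusted p = 0.36 with an estimated correlation). The cyclin gene CCNE2 changed by -2.76 ± 0.31 and the replication gene MCM10 by -2.66 ± 0.34, and the 1 rise was that of E2F1 (1.76 ± 0.25), a transcription factor of this phase. DNA repair genes had 32 falls and 4 rises (32 and 5 adjusted over the list alone) of 39, a median of -1.10, -0.46 after loess, and a camera adjusted p of 1.52e-06 (adjusted p = 0.323 with an estimated correlation). After loess 32 fell and 3 rose of these G2/M genes, 22 fell and 2 rose of the G1/S genes and 15 fell and 5 rose of the DNA repair genes. RAD50 changed by -2.54 ± 0.26 (-1.68 after loess). All these lists lay below random lists of like level, whose medians were -0.67, -0.68 and -0.63.

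Cytosolic ribosomal protein genes had a median change near 0, at values near the top of the signal range. Their medians were 13.12 in cells and 13.11 in microvesicles, the highest values of the arrays were 13.87 to 14.1, and whether saturation hides a change was not tested. Of 53 cytosolic ribosomal protein genes 2 rose and 1 fell (2 and 0 adjusted over the list alone), the median was -0.016 (camera adjusted p = 0.735, not passed), the mean was 0.10, and the median was 0.066 after loess and -0.17 with median centring. The rises were those of RPL27A and RPLP2, read from dimmer probe sets, which also lift the mean. The fall was that of RPL36A, at 3.78 in cells. Random lists of like level had a median of -0.36, below that of this list. The match is coarse at this level. Only 295 genes had a mean above 11, with a median change of -0.23, and the random lists drew on dimmer genes as well. Mitochondrial ribosomal proteins had 29 falls and 7 rises (29 and 6 adjusted over the list alone) of 72, with a median of -0.29 that turned to 0.36 after loess (4 fell and 35 rose) and 0.32 after quantile normalization. Camera's adjusted p was 0.0102 downwards (adjusted p = 0.594 with an estimated correlation) and 0.0338 upwards after loess (0.732 with an estimated correlation), and the list did not pass after quantile normalization (0.231). MRPL51 rose by 1.64 ± 0.18. Nuclear-encoded oxidative phosphorylation genes had 22 falls and 2 rises (18 and 2 adjusted over the list alone) of 68, and their median of -0.17 turned to 0.27 after loess (0 fell and 28 rose) and 0.20 after quantile normalization (camera adjusted p = 0.0334; adjusted p = 0.594 with an estimated correlation; 0.0554 without microvesicles replicate 4). Translation factors had 14 falls and 2 rises (the same adjusted over the list alone) of 34 with a median of -0.19, 0.034 after loess (6 fell and 11 rose) and 0.055 after quantile normalization (camera adjusted p = 0.0398; adjusted p = 0.512 with an estimated correlation). The call was lost without cells replicate 1 (0.057) or microvesicles replicate 4 (0.0576). For mitochondrial ribosomal proteins, oxidative phosphorylation and translation factors, random lists of like level had medians of -0.56, -0.40 and -0.35. The deposited medians of these lists lay above them, at percentiles 99.86, 99.88 and 94.74, so they fell less than genes of like level. EIF4G1, the scaffold of the cap-binding complex, changed by -1.64 ± 0.19 (-0.82 after loess). In contrast all 7 mitochondrially encoded mRNAs measured fell (7 adjusted over the list alone), with a median of -1.51, -1.04 after loess, where 5 fell and 0 rose (deposited values, camera adjusted p = 0.00907; adjusted p = 0.378 with an estimated correlation). ND6 changed by -3.53 ± 0.46 and ND4 by -1.80 ± 0.45.

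Splicing and ZNF genes were lower in microvesicles on median, by less after loess. Of 63 splicing genes 48 fell and 1 rose (the same adjusted over the list alone), with a median of -0.69, -0.13 after loess (17 fell and 7 rose) and -0.21 after quantile normalization (camera adjusted p = 3.78e-08; adjusted p = 0.36 with an estimated correlation). SRSF5 changed by -2.34 ± 0.30. ZNF genes had 188 falls and 108 rises (186 and 107 adjusted over the list alone) of 466 and a median of -0.25, against 0.28 in random lists of like level, -0.071 after loess (132 fell and 74 rose) and -0.055 after quantile normalization (camera adjusted p = 0.0249; adjusted p = 0.326 with an estimated correlation). ZNF518A changed by -3.39 ± 0.27 and ZNF703 by 2.22 ± 0.19. Replication-dependent histones, whose mRNAs mostly end without a poly(A) tail, had 14 falls and 6 rises (13 and 6 adjusted over the list alone) of 38 and did not pass camera (adjusted p = 0.198), with a median of -0.33, -0.15 after loess (11 fell and 4 rose) and 0.30 in random lists of like level. H2AC17 changed by -2.77 ± 0.35 and H1-5 by 1.39 ± 0.21. The nuclear-retained long noncoding RNAs had 7 falls and 4 rises (7 and 5 adjusted over the list alone) of 13 and a median of -0.64, -0.073 after loess (5 fell and 2 rose) and 0.24 in random lists of like level (camera adjusted p = 0.286, not passed). FTX changed by -3.58 ± 0.29 and MEG3 by 1.60 ± 0.17. Small nucleolar RNA host genes had 3 rises and 2 falls (the same adjusted over the list alone) of 9, a median of 0.37 against a mean of -0.23, and a camera adjusted p of 0.984. DANCR changed by 1.39 ± 0.20 and TAF1D by -3.74 ± 0.29. For the 13 small nucleolar RNAs 6 rose and 3 fell (the same adjusted over the list alone), with a median of 0.32 that turned to -0.10 after loess, where 3 fell and 5 rose (deposited values, camera adjusted p = 0.474). For the 53 microRNA genes 26 rose and 9 fell (the same adjusted over the list alone) with a median of 0.49 (camera adjusted p = 0.0636, not passed), 0.064 after loess (8 fell and 13 rose), where camera's direction turned, and 0.52 in random lists of like level. Probe sets of these last groups read host or precursor transcripts.

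Stress response and metabolic genes fell in larger number than they rose in the deposited values, with smaller falls after loess. Of 30 unfolded protein response genes 18 fell and 4 rose (the same adjusted over the list alone), with a median of -1.02, -0.25 after loess (13 fell and 4 rose) and -0.29 after quantile normalization (camera adjusted p = 0.000355; adjusted p = 0.349 with an estimated correlation). The disulfide isomerase gene PDIA3 changed by -3.85 ± 0.33 and the stress kinase EIF2AK3 by -3.34 ± 0.20, whereas the stress factors DDIT3 and ATF5 rose by 1.26 ± 0.38 and 1.01 ± 0.27 (1.996 and 1.79 after loess). Both were lower in cells replicates 4 and 5 (DDIT3 7.21 and 7.70, ATF5 7.36 and 7.60) than in the other cell arrays. The groups overlapped for DDIT3. Chaperones had 24 falls and 4 rises (the same adjusted over the list alone) of 31 and a median of -0.67, -0.17 after loess (11 fell and 6 rose) and -0.23 after quantile normalization (camera adjusted p = 0.000565; adjusted p = 0.326 with an estimated correlation). BAG3 changed by -1.77 ± 0.17 (-0.92 after loess) and HSF1 by 0.81 ± 0.18 (1.67 after loess). Proteasome subunits had 26 falls and 3 rises (the same adjusted over the list alone) of 38 and a median of -0.60, -0.024 after loess (5 fell and 6 rose) and -0.093 after quantile normalization (camera adjusted p = 0.000512; adjusted p = 0.446 with an estimated correlation). PSMC4 changed by -1.60 ± 0.24 (-0.75 after loess). In glycolysis 15 fell and 0 rose (16 and 0 adjusted over the list alone) of 23, with a median of -0.57, -0.17 after loess (4 fell and 2 rose) and -0.21 after quantile normalization (camera adjusted p = 0.00248; adjusted p = 0.378 with an estimated correlation). The pyruvate dehydrogenase kinase gene PDK1 changed by -2.48 ± 0.38 (-1.63 after loess). In cholesterol synthesis 13 fell and 1 rose (14 and 1 adjusted over the list alone) of 21, with a median of -0.86, -0.032 after loess (6 fell and 4 rose) and -0.063 after quantile normalization (camera adjusted p = 0.00371; adjusted p = 0.323 with an estimated correlation). SQLE changed by -2.99 ± 0.34 and MVK by 1.02 ± 0.15 (1.87 after loess). After loess camera still placed the unfolded protein response list below other genes (adjusted p = 0.0171, but 0.732 with an estimated correlation), and not the other lists of this paragraph. After quantile normalization it did so for this list (0.00542) and chaperones (0.0244).

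Signalling genes changed in both directions. BCR-ABL1 signalling genes had 12 falls and 4 rises (the same adjusted over the list alone) of 23, and their median of -0.40 turned to 0.34 after loess (4 fell and 6 rose) and 0.27 after quantile normalization (camera adjusted p = 0.0462; adjusted p = 0.378 with an estimated correlation). That call was lost without cells replicate 1 (0.0545), 2 (0.0574) or 3 (0.0549) or microvesicles replicate 5 (0.0808), and with the replicate number as a block (0.0576). JAK2 changed by -2.51 ± 0.24 and the adaptor gene GAB2 by 0.86 ± 0.22 (1.66 after loess). RAS-MAPK genes had 10 falls and 6 rises (the same adjusted over the list alone) of 30 and did not pass (camera adjusted p = 0.259), with a median of -0.033, 0.27 after loess (8 fell and 12 rose) and 0.33 after quantile normalization. The ribosomal S6 kinase gene RPS6KA3 changed by -2.50 ± 0.45. PI3K-AKT-mTOR genes had 15 falls and 1 rises (the same adjusted over the list alone) of 32 and a median of -0.18, 0.094 after loess (10 fell and 11 rose) and 0.14 after quantile normalization (camera adjusted p = 0.0334; adjusted p = 0.323 with an estimated correlation). RICTOR changed by -2.13 ± 0.29 (-1.30 after loess). JAK-STAT genes had 20 falls and 6 rises (the same adjusted over the list alone) of 33 and a median of -0.61, -0.067 after loess (12 fell and 7 rose) and 0.0082 after quantile normalization (camera adjusted p = 0.00784; adjusted p = 0.323 with an estimated correlation). SOCS7 changed by 2.36 ± 0.22 and the receptor gene IFNGR1 by -3.33 ± 0.26. Among apoptosis regulators 19 fell and 6 rose (the same adjusted over the list alone) of 35, and the median of -0.59 turned to 0.19 after loess (11 fell and 11 rose) and 0.21 after quantile normalization (camera adjusted p = 0.00311; adjusted p = 0.323 with an estimated correlation). The death receptor gene TNFRSF10A changed by -3.44 ± 0.24 and BCL2L2 by 1.05 ± 0.23 (1.85 after loess). Immediate early genes had 20 falls and 6 rises (the same adjusted over the list alone) of 38 and a median of -0.43, -0.029 after loess (11 fell and 8 rose) and -0.019 after quantile normalization (camera adjusted p = 0.0299; adjusted p = 0.378 with an estimated correlation; 0.438 after loess). KLF2 changed by 1.51 ± 0.24.

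Genes of vesicle formation and the cytoskeleton fell more often than they rose in the deposited values, where random lists of like level had medians of -0.56 and -0.51. After loess they rose more often (18 against 9 and 10 against 4), as did all genes together (5327 against 3610). Neither list passed camera after loess (adjusted p = 0.5995 and 0.4749). Of 54 vesicle formation genes 29 fell and 8 rose (the same adjusted over the list alone), and the median of -0.46 turned to 0.14 after loess and 0.098 after quantile normalization (camera adjusted p = 0.0117; adjusted p = 0.326 with an estimated correlation). The ESCRT gene VPS37B rose by 2.35 ± 0.18 and VPS36 changed by -2.24 ± 0.21 (-1.38 after loess). Cytoskeleton genes had 19 falls and 3 rises (the same adjusted over the list alone) of 43, and their median of -0.34 turned to 0.17 after loess and 0.11 after quantile normalization (camera adjusted p = 0.00927; adjusted p = 0.36 with an estimated correlation). The lamin gene LMNB1 changed by -3.30 ± 0.37 and the formin gene DIAPH1 by 0.95 ± 0.19 (1.59 after loess).

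Erythroid genes and markers of other blood cells had medians of opposite sign. Erythroid genes had 20 falls and 5 rises (the same adjusted over the list alone) of 40 and a median of -0.59, -0.041 after loess (6 fell and 8 rose) and -0.014 after quantile normalization (camera adjusted p = 0.0169; adjusted p = 0.378 with an estimated correlation). Random lists of like level had a median of -0.47. The blood group gene RHAG changed by -2.46 ± 0.23. Markers of other blood cells were higher in microvesicles. Of 23 platelet markers 16 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.00784; adjusted p = 0.323 with an estimated correlation). Of 22 myeloid markers 16 rose and 2 fell (the same adjusted over the list alone), with a median of 0.72 (camera adjusted p = 0.0194; adjusted p = 0.323 with an estimated correlation). TYROBP changed by 1.66 ± 0.28 and LYZ by -2.65 ± 0.30. Lymphocyte markers had 13 rises and 2 falls (the same adjusted over the list alone) of 24 and a median of 0.56 (camera adjusted p = 0.0471; adjusted p = 0.36 with an estimated correlation). CD22 changed by 1.35 ± 0.21 and the perforin gene PRF1 by -3.04 ± 0.19. The lymphocyte call was lost without cells replicate 1 (0.0578), 2 (0.0574) or 3 (0.0537) or microvesicles replicate 3 (0.0566), 4 (0.0576) or 5 (0.0751). The median cell value of these markers was 3.66, 3.49 and 3.96, and random lists of like level had medians of 0.56, 0.55 and 0.49. After loess their medians were 0.33 (0 fell and 9 rose), 0.30 (2 fell and 7 rose) and 0.37 (1 fell and 6 rose), and none of these lists passed camera (adjusted p = 0.384, 0.475 and 0.475). Interferon response genes had 16 rises and 8 falls (15 and 8 adjusted over the list alone) of 38 (median 0.38, camera adjusted p = 0.49). Cytokines had 19 rises and 3 falls (the same adjusted over the list alone) of 38 (median 0.51, camera adjusted p = 0.0607), and angiogenesis factors had 17 rises and 9 falls (the same adjusted over the list alone) of 40 (median 0.42, camera adjusted p = 0.22). None of these 3 lists passed. Their medians after loess were 0.13 (5 fell and 6 rose), 0.16 (4 fell and 7 rose) and 0.35 (6 fell and 13 rose), and random lists of like level had 0.42, 0.52 and 0.21. OAS1 rose by 1.36 ± 0.23 and ANGPTL4 by 1.57 ± 0.19, while VEGFA changed by -2.45 ± 0.32.

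**Figure D3:**
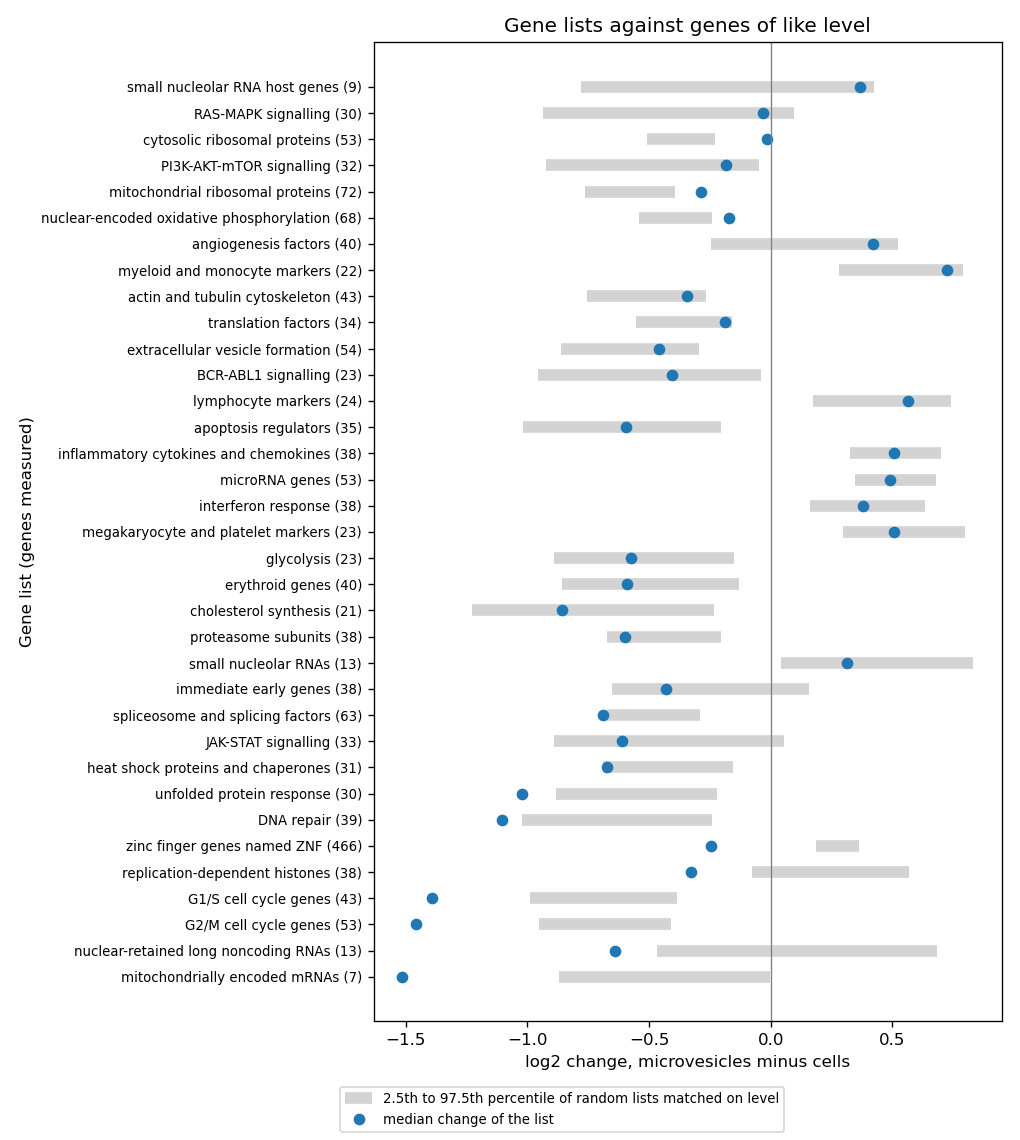
Median log2 change in microvesicles against cells of each gene list (blue points, number of genes measured in brackets) and the range that holds the central 95% of 10000 random lists matched on mean level (grey bars). G2/M genes lie at -1.46, below their bar, and cytosolic ribosomal proteins at -0.016, above theirs (0.066 after loess). The bar of the cytosolic ribosomal proteins rests in part on dimmer genes.

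In all, 25 of the 35 lists passed camera, 22 lower and 3 higher, and 0 passed with an estimated correlation (lowest adjusted p = 0.323, with 4 at an unadjusted p under 0.05), and fry, which asks whether the genes of a list move one way and does not compare them with other genes, called 32. After loess 8 passed camera, 7 lower and 1 higher, and 0 with an estimated correlation (lowest adjusted p = 0.732), and after a second quantile normalization 8, all lower. Of the genes named above, AKAP9, ECT2, EIF2AK3, SRSF5, ZNF518A, IFNGR1 and VPS36 each had 1 other probe set past the threshold in the opposite direction.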

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

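No test in this part was chosen after its result was seen. Of 100 splits of the 10 arrays drawn from 126, only the real one gave as many genes past the threshold (1 split with 13179, highest other 0) or as many at least 2-fold changed (1 split with 6142, highest other 0). The other splits mix the groups, so the group difference adds to the spread within them. Few calls there could be foreseen, and these counts cannot exclude chance. For gene lists 3 of 100 splits gave 25 or more, the real one included, and the highest other gave 25, so camera's preset correlation calls many lists under other splits as well.

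In 392 groups of 5 arrays (named genes, list medians and array measures), 22 had an array far from the other 4 by the size of its gap over the range, where chance gives about 1 in 20, or 19.6. Microvesicles replicate 5 was the far array in 8 of them and cells replicate 5 in 5.

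In microvesicles replicate 5 the gap made up 0.806 of the range for RPL36A (2.13 against 3.18 in the nearest array), 0.788 for TYROBP (6.53 against 5.27), 0.713 for VCAN (4.71 against 3.51), 0.731 for CDKN1B (7.56 against 8.41). It was 0.777 for IFNGR1 (4.47 against 5.56), 0.79 for PWAR6 (3.95 against 2.79), 0.739 for RAD52 (5.02 against 6.14) and 0.763 for the median of PI3K-AKT-mTOR genes (6.35 against 6.59). In cells replicate 5 it was 0.772 for ASB1 (6.52 against 6.34), 0.743 for ND6 (7.93 against 8.42), 0.816 for SOCS7 (6.36 against 6.67), 0.745 for BST2 (8.47 against 8.80) and 0.742 for the 18S control mean (11.7 against 12.16). Cells replicate 4 stood apart in AKAP9 (0.812, 7.85 against 8.13) and in the median of microRNA genes (0.853, 3.65 against 3.82), and cells replicate 1 in SDHA (0.787, 9.61 against 9.44) and CD9 (0.843, 5.19 against 5.88). Among other microvesicle arrays, replicate 4 stood apart in the medians of immediate early genes (0.768, 6.05 against 5.69) and glycolysis genes (0.79, 7.64 against 8.29), replicate 3 in MRPL23 (0.775, 8.93 against 9.21), replicate 2 in SLC2A1 (0.866, 4.29 against 5.75) and replicate 1 in DIAPH1 (0.751, 10.86 against 10.17).

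Probe sets with no gene listed, which no comparison above uses, held 1336 that were at least 2-fold higher in microvesicles and 1291 at least 2-fold lower, of 11721. The probe set with the largest rise went from 4.44 in cells to 11.85 in microvesicles (change 7.41 ± 0.25, limma adjusted p = 1.05e-09) and the next from 4.93 to 11.91 (6.98 ± 0.23). The largest falls were -4.86 ± 0.25 and -4.75 ± 0.32. A rise above 5 was seen in 7 of these probe sets and in 1 named gene, AP1G2-AS1 (6.35 ± 0.24 in 1 of its 2 probe sets, 0.997 in the other), which was chosen after its values were seen.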

How the results depend on the processing

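Loess normalization by level was chosen after the result was seen, and the other alternatives were planned. Genes past the threshold numbered 8500 after a second quantile normalization (5231 higher, 3269 lower), 7058 among genes above the median level (1477 higher, 5581 lower), 6344 among genes with a higher group mean of at least 6 (986 higher, 5358 lower), and 25902 probe sets when each was tested by itself, the last 3 because other numbers of features were tested. At least 2-fold changed were 4084 and 3874 genes under these filters. Lists past the threshold were 8 after quantile normalization, 8 after loess, 3 and 2 under the filters and 0 with an estimated correlation, and the cause was not tested. Leaving out each array gave 11664 to 13411 genes, 5967 to 6546 at least 2-fold changed, 22 to 25 lists, 0.602 to 0.832 for the ACTB control difference and 0.117 to 0.199 for GAPDH. The values do not settle whether the replicate numbers pair the samples. Same-number correlations of deviations ran from -0.028 to 0.12, over 0.1 in 2 of 5, but 4 of 5 cells and 3 of 5 microvesicles matched their own number best. With the number as a block 12974 genes, 6142 at least 2-fold changed and 24 lists passed (not BCR-ABL1 signalling, adjusted p = 0.0576), and the differences of 0.731 for ACTB and 0.171 for GAPDH had an exact sign-flip p of 0.0625, the smallest that 5 pairs allow. Centring on the bioB, bioC, bioD and cre controls was not run. The arrays carry no detection call, so signal over background limits dim genes to an unknown extent.

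Named genes that changed sign after quantile normalization were ABL1 (0.37), ACTB (0.0897), BCR (0.31) and GATA1 (0.26), and the same genes after loess (0.34, 0.15, 0.36 and 0.24). With the mean of all probe sets EPB41L4A-AS1 (-0.41), ERCC1 (-0.46), PRPF38A (-0.68) and SPG11 (-0.044) turned, and each has probe sets past the threshold in both directions. Camera's direction turned for cytosolic ribosomal proteins with median centring (median -0.17). After quantile normalization it turned for mitochondrial ribosomal proteins (0.32), oxidative phosphorylation (0.20), BCR-ABL1 signalling (0.27), RAS-MAPK (0.33), vesicle formation (0.098), cytoskeleton (0.11), interferon response (0.21) and small nucleolar RNAs (0.022). After loess it turned for translation factors (0.034), mitochondrial ribosomal proteins (0.36), oxidative phosphorylation (0.27), BCR-ABL1 signalling (0.34), RAS-MAPK (0.27), vesicle formation (0.14), cytoskeleton (0.17), small nucleolar RNA host genes (0.39), interferon response (0.13), small nucleolar RNAs (-0.10) and microRNA genes (0.064). Among genes above the median level it turned for translation factors (-0.19), mitochondrial ribosomal proteins (-0.29), oxidative phosphorylation (-0.17), RAS-MAPK (-0.15), PI3K-AKT-mTOR (-0.42), vesicle formation (-0.49), cytoskeleton (-0.34) and small nucleolar RNA host genes (0.094). With a higher group mean of at least 6 it turned for translation factors (-0.19), mitochondrial ribosomal proteins (-0.29), oxidative phosphorylation (-0.17), RAS-MAPK (-0.44), PI3K-AKT-mTOR (-0.64), vesicle formation (-0.58), cytoskeleton (-0.34), small nucleolar RNA host genes (0.094) and interferon response (-0.84). Under both filters the lists are set against brighter genes alone, which fell. Small nucleolar RNA host genes turned with the variance trend (0.37) and in 5 of the 10 fits without 1 array, those without cells replicate 1 (0.36), 3 (0.39) or 4 (0.43) or microvesicles replicate 1 (0.39) or 5 (0.38), while the medians over all 10 were 0.29 to 0.43. The cause of the other turns was not tested.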

Other observations

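The comparison of marker lists with random lists of like level, the test of each membrane protein family alone and the test of other probe sets were chosen after their results were seen, and the solute carrier and TMEM families were picked after values of some of their members had been looked at. Olfactory receptor genes, whose median cell value was 3.09, gave 59 rises and 2 falls among 102 genes, with a median change of 0.56 that became 0.16 after loess. Over all 376 solute carrier genes 135 rose and 125 fell, with a median of 0.20 (0.16 after loess), and over all 227 TMEM genes, which encode membrane proteins, 63 rose and 88 fell, with a median of 0.015 (0.013 after loess). The solute carrier genes with a mean of at least 6 gave 79 falls and 6 rises among 112, with a median of -1.03 (-0.30 after loess), and the TMEM genes of that level 65 falls and 6 rises among 90, with a median of -0.999 (-0.22 after loess).

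Platelet, myeloid and lymphocyte marker lists were higher in microvesicles. RNA of platelets or white blood cells would bring their abundant transcripts. The median change of PF4, PPBP, S100A8, S100A9, LYZ, GNLY, NKG7 and CD3E lay -0.16 from that of olfactory receptor genes. S100A8 (1.46) and CD3E (0.90) rose while LYZ fell by 2.65 from 7.50 in cells. A median over transcripts of several cell types cannot show RNA of a single type. It argues only against RNA of all these cells together as the source of the lists' rise. Among all genes in microvesicles PF4 and PPBP lay at percentiles 21.76 and 4.41, and S100A8, S100A9 and LYZ at 28.83, 8.89 and 45.85. GNLY, NKG7 and CD3E lay at 30.87, 24.18 and 37.6. All of these lie below the median gene, but without a detection call a smaller amount of RNA of a single type stays open. For a shift of dim probe sets by the normalization, a bound set beforehand counted a largest list median above 0.3 after loess against it, and the value, that of lymphocyte markers, was 0.37. That bound was set wrongly, since loess left all genes with a mean between 4 and 5 at 0.38 and the bootstrap interval of the list median ran from 0.11 to 0.58, so this explanation stays open. A candidate explanation is a shift shared with other genes of like level, as the highest of the lists' percentiles among random lists matched on level was 92.35, a comparison made with the values already known.

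Solute carrier and TMEM genes with a mean of at least 6, but not the families as a whole, were lower in microvesicles. Their joint median of -1.02 lay at percentile 0.21 of random lists matched on level, whose median was -0.79. It lay at percentile 0.07 of lists matched on level and gene span, known for all 202 genes, whose median was -0.76. TMEM genes alone lay at percentiles 1.7 and 0.08, solute carriers alone at 3.94 and 8.08. As the families were picked after values of members had been seen, these percentiles exclude neither level nor span, and both stay open. A biological difference and the larger 3' to 5' difference of the control probe sets in microvesicles were not tested and stay open too.

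Genes at least 2-fold higher in microvesicles may owe their rise to a single probe set. Their other probe sets with a mean of at least 6 covered only 36 of the 2221 genes. These 53 probe sets had a median change of 0.70 (quartiles 0.13 and 1.39), with 29 past the threshold upwards and 7 downwards. The value lies between the bounds of 0.3 and 1 set for the test, so a rise of the gene and of 1 probe set cannot be told apart. For genes at least 2-fold lower, 1233 of 1339 other probe sets passed in the same direction and 9 in the opposite one. Genes of such levels mostly fell in any case. Of 2379 genes with a mean between 6 and 7, 1443 were lower and 284 higher, and of 1816 between 7 and 8, 1262 and 112. Part of the agreement downwards can therefore come from level, which also works against agreement among the other probe sets of the risen genes. No biological explanation was tested.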
